A study of Homo sapiens with 3 samples.

How the data were processed

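RNA from anti-HA RNA immunoprecipitation (Magna RIP kit) of LM9 cells was hybridised to a 1-colour lncRNA expression array, 1 array for each of HA-3'-NFYB, HA-5'-NFYB and control lentivirus. Per the labels' protocols, RNA was reverse-transcribed from oligo-dT primers and labelled with cyanine-3. The deposited files hold spot intensity values from Agilent Feature Extraction 11.0.1.1 with protocol GE1_1100_Jul11, per the file headers, and the grid names build hg19. Per the file headers, the software subtracted background and removed spatial trends within each array. The authors' values are not normalized between arrays. The files also hold other values, flags of 0 or 1 for outlier, saturated and well-above-background spots, per the file headers. Any processing by the authors beyond that is not given in the sources used here.

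Each array had 61184 spots. Control-type spots, 600 spots of 60 negative control probes and spots flagged as outliers were left out, which removed 121 probes on at least 1 array. No spot was saturated. Spots of a probe were averaged on the log2 scale of the processed intensity, and each array's 75th percentile over non-control probes was subtracted. That percentile was 271.5 units on the HA-3'-NFYB array, 177.8 on the HA-5'-NFYB array and 161.4 on the control array. A log2 ratio is the difference of these values between arrays. A probe not well above background on 1 of the arrays compared entered as a bound, its brighter side over the higher of the dim array's lowest well-above-background signal and the probe's own signal. Such a ratio is written "at least N-fold". Probes dim on both arrays were not compared. A probe above background on 1 array only was also left out when its bound did not point to that array. This filter depends on the ratio, so shares of the probes compared leave such probes out. The threshold was 2-fold. With both constructs, each ratio had to pass it on its own.

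With 1 array per group there was no test in the main comparisons and no p-value was computed. The precision is limited by the number of arrays; the SDs given are over the spots of 1 array or of the arrays compared. As an alternative, limma 3.58.1 in R 4.3.3 was fitted with the constructs as 2 samples of 1 arm against the control. Gene lists were described by their median and its percentile among 10000 random lists drawn from probes of like mean signal, in 50 bins. The noise for simulated arrays was taken from the difference between the constructs. Tested on 26265 simulated probes for both constructs against control, the 2-fold rule recovered 88% of 4-fold higher and 78% of 4-fold lower probes, and 100% of the 16-fold ones. It also called 12.3% of simulated probes with no difference. The changed probes, 50 for each fold and direction, were drawn only from those above the median signal. The noise left out any difference between slides, so these rates may be too favourable for the real arrays. limma recovered 8% and 4% of the 4-fold and 70% and 86% of the 16-fold probes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

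The 20 mRNA probes were named through their RefSeq accessions, all of which matched the reference gene table (assembly GRCh38.p14, used for names only). The rule fixed before the data were examined was written for gene symbols, with a fallback to at most 2 probe IDs up and 2 down per comparison where the files name no gene. The fallback was used, and 18 of the named mRNAs are given beside it; the other 2 are not reported here and were left out of the gene lists. Of the 22 lists fixed beforehand, only the cytosolic ribosomal protein and housekeeping lists had named members. The other lists cover NF-Y subunits, NF-Y cell cycle targets, NF-Y and chromatin partners, lipid synthesis, the unfolded protein response, antigen presentation, immune checkpoints, chemokines, interferon response, epithelial-mesenchymal transition, hepatocyte genes, leukocyte, endothelial and stromal, and erythroid markers, cancer-associated lncRNAs, small nucleolar RNA host genes, structured RNAs, mitochondrial genes, histones, and heat shock, and none of their members was named. The planned comparison of lncRNAs with protein-coding RNAs was not made, because the class of the probes is unknown here.

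Alternatives were normexp background correction with an offset of 50, scaling on the median of probes above background on all arrays, quantile normalization, no scaling, only probes above background on all arrays, no filter on dim probes, and limma. Scaling on the 75th percentile of probes above background on all arrays and quantile normalization of the GAPDH and PGK1 probe pairs were added after seeing the data. The normexp alternative was planned on mean spot signals, which the files used here lack, and was run on median spot signals.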

Results

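RNA bound in the anti-HA immunoprecipitate was measured in LM9 cells, a hepatocellular carcinoma line that the labels describe as highly metastatic. The cells had been infected with a control lentivirus or with a lentivirus for HA-tagged NFYB, the beta subunit of the CCAAT-binding transcription factor NF-Y. There were 2 NFYB constructs, named HA-3'-NFYB and HA-5'-NFYB. The labels do not say what 3' and 5' refer to. Each construct and the control had 1 array, so no value below has a replicate and no spread within a group could be had. No input RNA is listed, so the values are levels in the precipitate and not enrichment over input. The array carried 58844 probes with a value on all 3 arrays. Of these, 58824 have only the maker's probe ID, so their genes and their class, lncRNA or protein-coding, are unknown here. The other 20 are probes of named mRNAs, each printed as 10 spots, and 18 of these are reported.

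Signal was well above background for 39006 probes (66.2%) on the HA-3'-NFYB array, 35928 (60.9%) on the HA-5'-NFYB array and 28605 (48.6%) on the control array. Of the spots of the negative control probes, 7.6%, 5.3% and 3.3% carried the same flag, in the same order. The median signal was 45.5, 33.1 and 25.0 units in that order. A total of 26265 probes were above background on all 3 arrays. Another 7795 were above background on both construct arrays and not on the control array, and 711 on the control array alone. Per the file headers both constructs shared 1 scan, while the control came from another scan on another day. Slides were told apart by scan only, so the control is taken here as being on another slide. Construct and slide or scan therefore cannot be told apart in any comparison with control.

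The first question was which RNAs came down with both forms of HA-tagged NFYB more than with the control virus. Among the 18 named mRNAs, 2 were at least 2-fold higher with both constructs. ARHGDIA was 3.92-fold higher with HA-3'-NFYB and 2.31-fold higher with HA-5'-NFYB, at log2 ratios of 1.97 ± 0.04 and 1.21 ± 0.05 (SD over spots of the arrays compared, which covers the spots only). MTX1, which encodes a mitochondrial outer membrane protein, was 2.34-fold and 2.92-fold higher. Both mRNAs were higher with both constructs under all 6 settings of background and scaling.

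In the same comparison 8 of the 18 mRNAs were at least 2-fold lower with both constructs. EIF3D, a subunit of translation initiation factor eIF3, was 3.37-fold lower with HA-3'-NFYB and 7.48-fold lower with HA-5'-NFYB. COX4I1, a subunit of cytochrome c oxidase, was 3.24-fold and 2.91-fold lower. DYNLL1, a dynein light chain, was 3.09-fold and 2.38-fold lower, and RACK1, a scaffold protein of the ribosome, 2.80-fold and 2.33-fold lower. The cytoskeletal actin ACTB was 2.67-fold lower with HA-3'-NFYB and just over 2-fold lower with HA-5'-NFYB. Of the mRNAs lower with both constructs, EIF3D, COX4I1 and RPL10 had log2 ratios below 0 with both constructs under all 6 settings. With quantile normalization the 5' construct ratios of ACTB, DYNLL1, RACK1, RPLP1 and RPS18 lay above 0, and the counts became 4 mRNAs higher and 1 lower with both constructs. With normexp and with scaling on the median, 6 mRNAs were at least 2-fold lower with both, without ACTB and RPL10. Without scaling 1 mRNA was, and 2 were with the 75th percentile taken over the probes above background on all arrays.

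Of the 22 gene lists fixed before the data were examined, 2 had members named in the files. The 3 named cytosolic ribosomal protein mRNAs of the 32 on that list, RPS18, RPL10 and RPLP1, were all at least 2-fold lower with both constructs, but RPL10 was so only with the main setting and quantile normalization, and RPS18 and RPLP1 only with the main setting, normexp and scaling on the median. Their median log2 ratio was -1.31, at the 48.0th percentile of 10000 random lists of the same size and signal. With quantile normalization this median was -0.050. The 3 reported housekeeping mRNAs of 19, ACTB, GAPDH and PGK1, had a median of -0.86 at the 74.98th percentile, and 0.46 with quantile normalization. ACTB alone among these was at least 2-fold lower with both constructs. GAPDH, a glycolytic enzyme, had log2 ratios of -0.80 and -0.93, and both were above 0 with quantile normalization. Its direction also differed between probes, since the quality-control 5' probe of GAPDH had ratios of 1.95 and 0.65 and the 3' probe -0.68 and -1.13. No probe was named for the NF-Y subunits, so the level of NFYB itself was not analysed here. The same holds for the hepatocyte, leukocyte, endothelial and stromal, and erythroid markers, and for the cancer-associated lncRNAs.

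**Figure D1:**
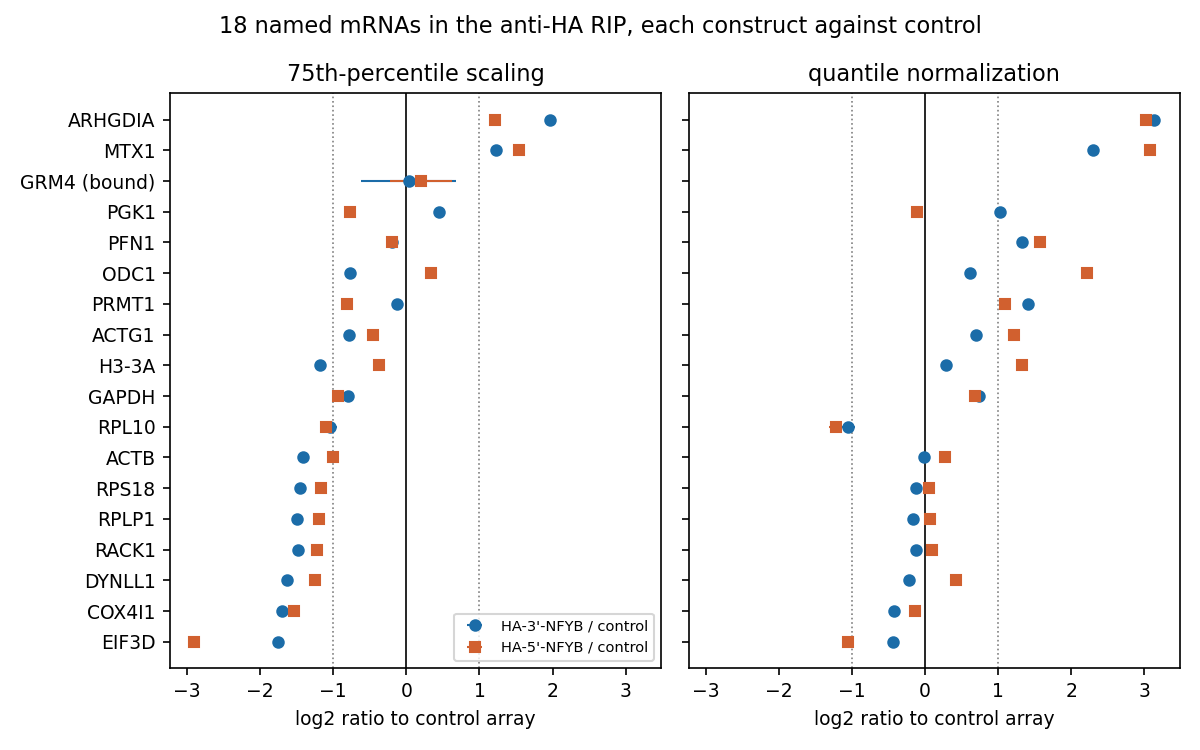
Log2 ratio to the control array (horizontal axis) of 18 named mRNAs (vertical axis) for HA-3'-NFYB (circles) and HA-5'-NFYB (squares), with 75th-percentile scaling on the left and quantile normalization on the right. Bars are the SD over spots and dotted lines mark 2-fold; GRM4 enters as a bound on the left and has no value on the right. ARHGDIA and MTX1 lie above 1 in both panels, while several abundant mRNAs, such as ACTB and RPS18, lie at or below -1 on the left and near 0 on the right.

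Over all probes, 4866 of the 31854 compared (15.3%) were at least 2-fold higher with both constructs, and 7896 (24.8%) at least 2-fold lower. A further 339 were at least 2-fold higher with 1 construct and at least 2-fold lower with the other. The share of higher calls among these was 38.1%, but 58.2% without scaling and 56.1% when the 75th percentile was taken over the probes above background on all arrays. Which direction held more probes therefore depended on the scaling. Over only the 26265 probes above background on all arrays, where no ratio is a bound, 14.3% were higher and 24.4% lower with both constructs. Among probes high with both constructs, ranked by the smaller ratio, ASHGA5P006602 had the highest measured ratios to control, 562-fold with HA-3'-NFYB and 695-fold with HA-5'-NFYB, and ASHGA5P058638 followed at 278-fold and 162-fold. Probe ASHGA5P024308 was not well above background on the control array and was at least 436-fold and 405-fold higher. In the other direction, ASHGA5P052641 was 1643-fold and 1715-fold lower, and ASHGA5P025217 was 1271-fold and 1159-fold lower. Unlike the named mRNAs, probes with only the maker's ID have no repeated spots on an array, so their ratios have no SD over spots.

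The ratios of the constructs to control went together across probes. Over the 26265 probes above background on all arrays, Pearson's r was 0.85 and Spearman's rank correlation 0.83, with the same sign for 83.6% of probes. Probes are not independent replicates, and both ratios share the 1 control array. In 3 simulated arrays with no difference and with the noise seen between the constructs, r was 0.51 and the sign was shared by 67.1%. The covariance was 2.90 against 0.53 in the simulation, a difference of 2.38. In the simulation 1671 higher and 1747 lower calls were shared, against 3744 and 6411 observed among the same 26265 probes. Among the 31854 probes compared with both constructs, bounds included, 6670 were at least 2-fold higher with HA-3'-NFYB and 7195 with HA-5'-NFYB, and 9612 and 10394 were lower. Independent lists of these sizes would share 1507 higher and 3136 lower, against the 4866 and 7896 observed. The simulated noise comes from arrays of 1 slide and leaves out any difference between slides, and the 1 control array could not be split. All or part of the excess may therefore come from the control array or its slide.

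**Figure D2:**
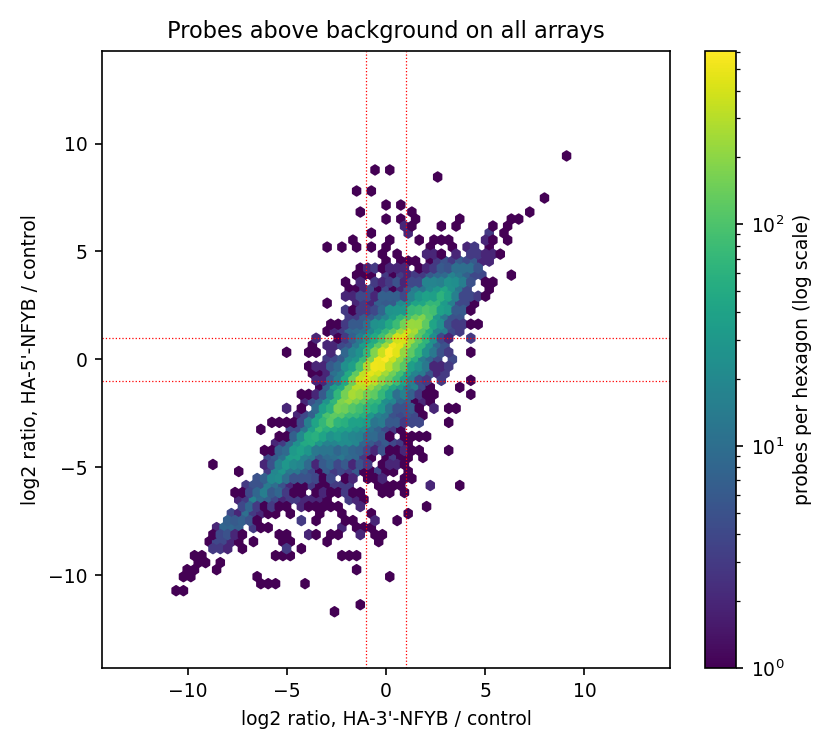
Log2 ratio to control of HA-5'-NFYB (vertical axis) against that of HA-3'-NFYB (horizontal axis) for the 26265 probes above background on all arrays. Colour gives probes per hexagon on a log scale and dotted lines mark 2-fold. The points lie along the diagonal, with Pearson's r at 0.85. The filter leaves out probes dim on any array, among them the 7795 above background on both construct arrays and not on the control array.

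The next question was what each construct brought down when taken alone. For HA-3'-NFYB, 2 of the 18 mRNAs, ARHGDIA and MTX1, were at least 2-fold higher than in control and 9 at least 2-fold lower. The counts were 5 higher and 1 lower with quantile normalization, and 3 higher and 1 lower without scaling. Beside the 8 mRNAs lower with both constructs, the ninth was H3-3A, which encodes the histone variant H3.3 and had a log2 ratio of -1.19, but 0.29 with quantile normalization. Over all probes 6827 of 32676 were at least 2-fold higher and 9612 lower. Of these, 1498 and 895 rest on a bound because 1 side was not well above background. The share of higher calls was 41.5%, but 70.5% without scaling and 54.8% with the 75th percentile over probes above background on all arrays. The median log2 ratio of probes measured on both arrays was -0.23, and it was 0.52 without scaling and 0.097 with that percentile.

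For HA-5'-NFYB the same 2 mRNAs were at least 2-fold higher than in control and 8 at least 2-fold lower. The counts were 7 higher and 2 lower with quantile normalization, and 2 higher and 2 lower with the 75th percentile over probes above background on all arrays. H3-3A was not among the 8, at -0.38. ODC1, the first enzyme of polyamine synthesis, had a log2 ratio of 0.34 with this construct and -0.77 with HA-3'-NFYB, but both were above 0 with quantile normalization, at 2.22 and 0.62. Over all probes 8005 of 34196 were at least 2-fold higher and 10394 lower, of which 2540 and 1884 rest on a bound. The share of higher calls was 43.5%, but 61.0% with the 75th percentile over probes above background on all arrays. The median log2 ratio was -0.24, and 0.25 with that percentile. Probe ASHGA5P053861 was 495-fold higher than in control with HA-5'-NFYB and 1.13-fold higher with HA-3'-NFYB. Probe ASHGA5P043834 was 3809-fold lower with HA-5'-NFYB and 6.19-fold lower with HA-3'-NFYB. Its signal on the HA-5'-NFYB array was 26.0 units, where the lowest well-above-background signal was 17.3.

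Both constructs could be compared within 1 slide. PGK1, a glycolytic enzyme, was 2.32-fold higher with HA-3'-NFYB than with HA-5'-NFYB, at a log2 ratio of 1.21 ± 0.03 (SD over spots), and EIF3D was 2.22-fold higher. ODC1 was 2.16-fold lower with HA-3'-NFYB. These 3 directions held under all 6 settings of background and scaling. The other 15 mRNAs lay within 2-fold, among them ARHGDIA at 0.76, H3-3A at -0.81 and PRMT1, a protein arginine methyltransferase, at 0.69. PFN1, an actin-binding protein, was at -0.0053. Over all probes 4485 of 38081 were at least 2-fold higher with HA-3'-NFYB and 4577 lower, of which 903 and 1216 rest on a bound. The share of higher calls was 49.5%, but 82.0% without scaling and 39.2% with the 75th percentile over probes above background on all arrays. Over only the probes above background on all arrays it was 61.2%, at 3356 higher and 2126 lower. Probe ASHGA5P039807 was 1084-fold higher and probe ASHGA5P007362 638-fold lower with HA-3'-NFYB. ASHGA5P039807 had 17.7 units on the HA-5'-NFYB array, where the lowest well-above-background signal was 17.3. ASHGA5P007362 had 42.8 units on the HA-3'-NFYB array. Both ratios thus rest on a dim signal from a spot that is not repeated. The log2 ratios between the constructs had an SD of 1.02 over the 26265 probes, against 1.76 for HA-3'-NFYB and 1.94 for HA-5'-NFYB to control, but only the first of these lies within 1 slide.

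The array's quality-control probes name a 3' and a 5' probe of human GAPDH and PGK1, as far as the suffix of the probe name tells. On the control array the GAPDH 5' probe gave 12.9% of the signal of the 3' probe. This was 44.5% on the HA-5'-NFYB array and 80.5% on the HA-3'-NFYB array, which are 3.43 and 6.22 times the control share. For PGK1 the shares were 0.726%, 1.58% and 2.41%, so 2.18 and 3.32 times that of control. These ratios within an array do not depend on a scaling factor, but they do depend on how an array's signal maps to amount. With quantile normalization the 5' to 3' difference over control went from 2.64 to 2.39 for GAPDH with HA-3'-NFYB and from 1.78 to 1.74 with HA-5'-NFYB, on the log2 scale. For PGK1 it went from 1.73 to 0.62 with HA-3'-NFYB and from 1.13 to -0.57 with HA-5'-NFYB, so this last direction was lost. The constructs also differed from each other within their slide, by 0.86 ± 0.05 for GAPDH and 0.61 ± 0.05 for PGK1 on the log2 scale (SD over spots).

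**Figure D3:**
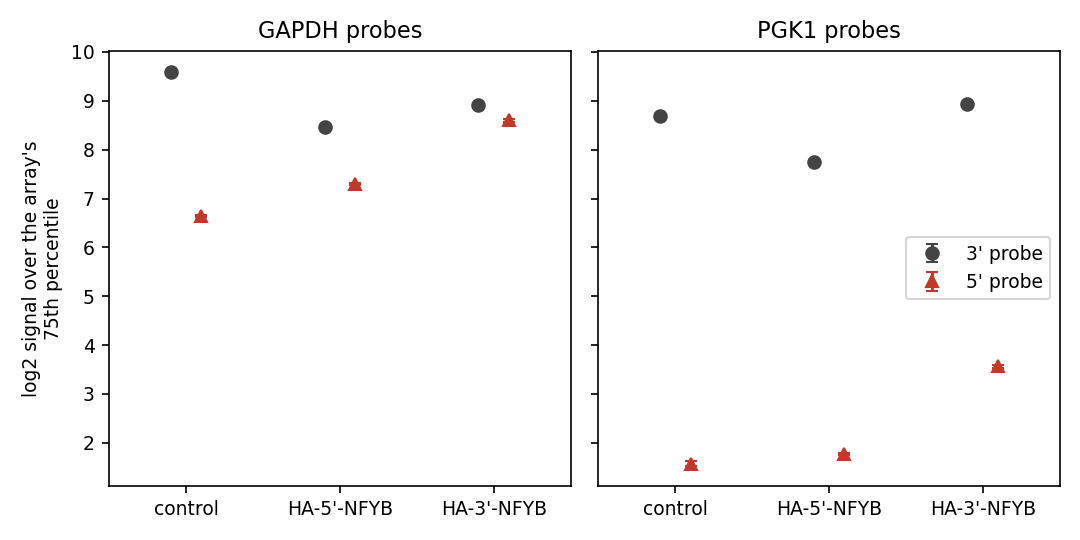
Log2 signal over the array's 75th percentile (vertical axis) of the 3' (circles) and 5' (triangles) probes of human GAPDH and PGK1 on the control, HA-5'-NFYB and HA-3'-NFYB arrays; bars are the SD over spots of 1 array. The 5' probe of GAPDH approaches the 3' probe on the HA-3'-NFYB array, at 80.5% of its signal, and lies far below it on the control array, at 12.9%.

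The ratio to control varied with signal. With the probes parted into 10 equal bins by signal, the median log2 ratio in the brightest bin was -1.06 for HA-3'-NFYB and -1.32 for HA-5'-NFYB, and in bin 6 it was 0.29 and 0.14. With quantile normalization the brightest bin lay above 0, at 0.23 and 0.27, and the dimmest bin was lowest, at -0.69 and -0.76. The bins hold only probes above background on all arrays. The lowest such signal was 27.3 units on the control array, against 16.7 on the HA-3'-NFYB and 17.3 on the HA-5'-NFYB array. In the dimmest bin this filter by itself can favour ratios below 0. Most of the named mRNAs lie in the bright range, with signals above 10000 units on the control array for all but MTX1, PGK1, RPL10 and GRM4. GRM4, a glutamate receptor, was not well above background on the control array.

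**Figure D4:**
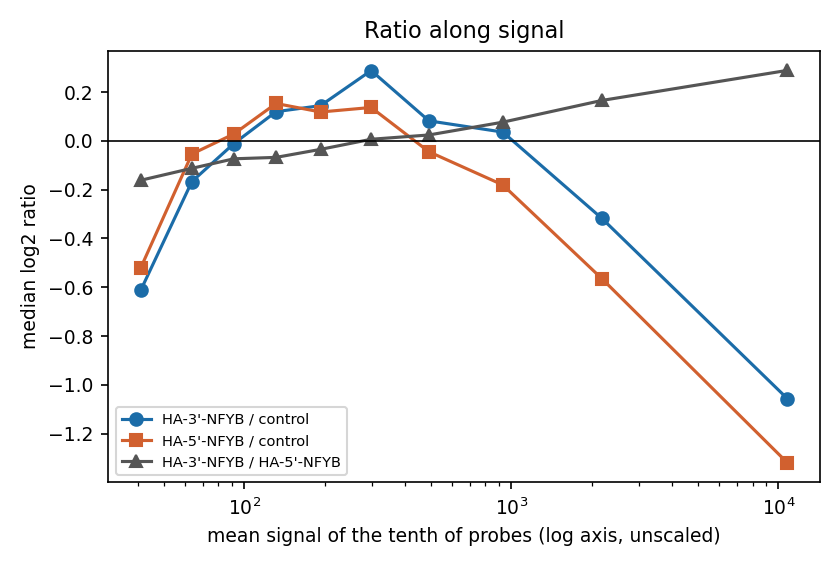
Median log2 ratio (vertical axis) of HA-3'-NFYB to control (circles), HA-5'-NFYB to control (squares) and HA-3'-NFYB to HA-5'-NFYB (triangles) in 10 equal bins of the probes above background on all arrays, placed by their mean signal in array units (horizontal log axis). With the 75th-percentile scaling plotted, both ratios to control are lowest in the brightest bin, at -1.06 and -1.32, but with quantile normalization (not plotted) they are 0.23 and 0.27 there. The ratio between the constructs goes from -0.16 in the dimmest bin to 0.29 in the brightest, against -0.0058 and -0.050 with quantile normalization.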

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

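The tests of slide and scan, the test on the HA-3'-NFYB array alone, and all tests on the GAPDH and PGK1 probe pairs were chosen after the results were seen; the tests of background, signal distributions and position on the array were written beforehand.

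Signal appeared above the control array in quality-control probes that entered no comparison. On the HA-3'-NFYB array the mouse PGK1 5' probe was 5.24-fold higher than on the control array (log2 2.39), the rat GAPDH 5' probe 5.33-fold higher (log2 2.41) and the rat PGK1 5' probe 4.31-fold higher (log2 2.11), after scaling. The mouse GAPDH 5' probe was not higher, at -0.27, with a signal of 96.3 units. On the HA-5'-NFYB array the same 4 probes had log2 ratios of 0.71, 0.56, 0.39 and -0.16.

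These probes go with the higher 5' to 3' share of human GAPDH and PGK1 on the construct arrays. Compression of the brightest probes, or a response that differs between arrays, stays open. With HA-5'-NFYB the 3' probes of both genes were dimmer than on control, unscaled (log2 -0.99 for GAPDH and -0.79 for PGK1), which had argued against compression. The criterion was then reset, after the result was seen, to ask that quantile normalization keep the difference of both genes. It kept GAPDH at 1.74 but turned PGK1 to -0.57, so the test decides nothing for the pair of genes. With HA-3'-NFYB the unscaled 3' probe was 1.01 brighter for PGK1 and 0.07 for GAPDH. A difference between slides or scans cannot explain the difference between the constructs, which share a slide and differed by at least 0.61 for human GAPDH and PGK1. Differences between arrays of that slide stay open, since each construct has 1 array and the SD covers spots only. For constructs against control, slide and scan cannot be told apart from the construct, since 0 slides hold both. RNA fragmentation, or labelling that starts at the 3' end, stays open too: the mouse PGK1, mouse GAPDH and rat GAPDH pairs also had a higher difference on both construct arrays, by 0.62 at the least (SD over spots 0.35), but they probe the same genes, the criterion was reset from mouse PGK1 alone after mouse GAPDH had put the constructs in the other order (1.13 for HA-3'-NFYB and 2.30 for HA-5'-NFYB), and so they decide nothing. No biological explanation was tested, and the construct itself stays open.

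More probes were well above background on the construct arrays than on the control array, 1.36 times for HA-3'-NFYB and 1.25 times for HA-5'-NFYB among probes with a value on all arrays. Spots of the negative control probes also passed more often there, at 7.6% with HA-3'-NFYB and 5.3% with HA-5'-NFYB against 3.3% on the control array. The software's own value for the background spread of negative controls, per the file headers, was 4.36 units on the control array against 2.71 and 2.73. It was not computed here from the negative control probes that were left out. At the control array's lowest well-above-background signal, 27.3 units, the ratio was 1.09 for HA-5'-NFYB, which goes with the higher background as the main source there. For HA-3'-NFYB the ratio was 1.20, where background alone leaves an excess. The limit was applied to unscaled signals, and the HA-3'-NFYB array was brighter, at a 75th percentile of 271.5 units against 161.4 on the control array. The count therefore does not separate this excess from the overall brightness of the array. Slide and scan cannot be told apart from the construct here, as a corner oligonucleotide that does not come from the sample gave log2 ratios to control of -3.56 and -3.59, unscaled. The construct itself stays open.

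For the 4866 probes at least 2-fold higher with both constructs, quantile normalization left 92.5% at 2-fold or more. It also raised the median log2 ratio to control, from -0.23 to -0.053 with HA-3'-NFYB and from -0.24 to -0.063 with HA-5'-NFYB. Such a rise favours keeping higher calls, so the test does not decide whether different signal distributions caused the set. Of the probes lower with both constructs, quantile normalization left 80.2%. Normexp left 58.1% of the higher set. Damage or uneven hybridization at 1 place is argued against by the nearest spots, which were such probes 0.990 times as often as any compared probe. Slide and scan stay open with the construct and cannot be told apart from it, since 0 slides hold the control and a construct.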

How the results depend on the processing

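The scaling on the 75th percentile of probes above background on all arrays and the added run on probe pairs were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Scaling on the E1A spike-in probes was not run because 0 of the 10 were above background on all arrays. Every spot of the control probes ERCC-00012_90, ERCC-00043_129 and ERCC-00062_278 was above background on all arrays, but scaling on these was not tried. The mean or range over a gene's probes and the lncRNA shares with their matched version were not run, since no named gene had several non-control probes and the class of the probes is unknown here. The correlation of the ratios was 0.82 with quantile normalization and 0.85 with normexp. The other scalings subtract a constant per array, which cannot change this correlation, so they do not test it. Without the filter it was 0.74 over all 58844 probes, which adds probes near background by construction. Scaling on the median of probes above background left every count within 1.5 times.

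Counts of probes per comparison that moved by over 1.5 times are as follows, and the cause was not tested unless stated. Normexp gave 4486 probes higher with HA-3'-NFYB, 5035 with HA-5'-NFYB and 2894 with both constructs, and 2403 lower with HA-3'-NFYB than HA-5'-NFYB. Without scaling 13474 were higher and 5643 lower with HA-3'-NFYB, 5213 lower with both, and 10001 higher and 2197 lower with HA-3'-NFYB than with HA-5'-NFYB; the brighter HA-3'-NFYB array shows the cause. With the added scaling 7337 were higher with both. Without the filter, by construction over more probes, 11492 were higher and 20910 lower with HA-3'-NFYB, 13704 higher with HA-5'-NFYB, 8582 higher with both and 7956 lower with HA-3'-NFYB than HA-5'-NFYB; with only probes above background on all arrays this last count was 2126. The limma fit had 1 residual degree of freedom, which came from the difference between the constructs alone. The 1 control array gives no spread, so the p-values of this fit do not measure the uncertainty of construct against control. No calls are drawn from it.

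Probes called in opposite directions numbered 166 with normexp and 1146 without the filter, against 339. Named mRNAs at least 2-fold lower, 9 with HA-3'-NFYB, 8 with HA-5'-NFYB and 8 with both, numbered 1, 2 and 1 with quantile normalization, and without scaling 1 with HA-3'-NFYB and 1 with both; the added scaling gave 2 with HA-5'-NFYB and 2 with both. Those higher, 2 in each of these comparisons, numbered 5, 7 and 4 with quantile normalization. Between the constructs, 2 higher and 1 lower became 1 and 2 with quantile normalization, 4 and 0 without scaling, 2 and 0 with normexp, and 1 and 1 with the added scaling.

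Quantile normalization gave a median of -0.050 for the ribosomal list and 0.46 for the housekeeping list, and the added scaling -0.90 for the ribosomal list. Of ratios of at least 2-fold, it also reversed those to control of ACTB (0.27), DYNLL1 (0.42), RACK1 (0.10), RPLP1 (0.066) and RPS18 (0.056) with HA-5'-NFYB, and of H3-3A (0.29) with HA-3'-NFYB; smaller mRNA ratios turned too. In the added run it reversed the 5' to 3' difference over control of PGK1 with HA-5'-NFYB (-0.57). No ratio of an mRNA that was at least 2-fold reversed under the other settings of background and scaling. Dim probes limit the rest: 48.6% to 66.2% of probes were above background.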

Other observations

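Among the 26265 probes above background on all arrays, 781 were at least 16-fold lower with both constructs and 62 at least 16-fold higher, and 505 and 98 with quantile normalization. With bounds included, the numbers were 866 and 86 of 31854 probes. These counts do not settle a direction of the large ratios, because the control array's higher limit of detection caps the ratios of probes dim on it, of which 7795 were above background on both construct arrays. Between the constructs, 136 probes were at least 16-fold higher and 75 at least 16-fold lower with HA-3'-NFYB.

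The corner oligonucleotide of the array gave 60634 units on the control array, against 5134 on the HA-3'-NFYB and 5049 on the HA-5'-NFYB array. Of the 10 E1A spike-in probes, E1A_r60_a107 gave 239 units on the control array, with every spot above background. It gave 5.91 and 7.18 units on the HA-3'-NFYB and HA-5'-NFYB arrays, with none above it. Other control probes went the other way. E1A_r60_a22 gave 15.2 units on the control array, with no spot above background, and 27.0 and 20.9 on the construct arrays in the same order. ERCC-00097_63 gave 8.28 units on the control array, and 54.2 and 39.7 on the construct arrays. The brightest 1% of probes held 60.5% of the signal on the control array, 55.0% on the HA-3'-NFYB array and 53.0% on the HA-5'-NFYB array.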
